A study of Mus musculus with 7 samples.

How the data were processed

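Neural tubes of ICR mouse embryos at stage E11.5 were dissociated with trypsin and reporter-positive cells were purified by fluorescence-activated sorting, per the labels' protocols, which name GFP alone, while the description of each Ptf1a library names mCherry. RNA was isolated with a Zymo kit and libraries were made by Illumina's mRNA-seq procedure, per the labels' protocols, and whether the libraries keep strand is not given in the sources used here. There were 7 libraries, 2 from Ascl1GFP/+ embryos and 2 from Ascl1GFP/GFP embryos sorted for GFP, and 1 from Ptf1aCre/+ and 2 from Ptf1aCre/Cre embryos, both carrying a Ptf1a::mCherry transgene and sorted for mCherry. The group of each library was taken from its title, since the genotype label of the Ptf1a heterozygote names both genotypes. The labels do not say whether libraries of 1 group came from separate embryos or litters.

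CASAVA, TopHat2 2.0.8, Cuffdiff 2.1.1 and the mm9 build are named in the submitters' processing notes, without the gene annotation or settings. All values came from 1 table of the whole series. Per the file headers it gives, for each gene and for Ascl1 and Ptf1a in turn, a WT value, a mutant value, a fold change, a q-value and a yes or no for significance. The WT and mutant values are 1 number per group and were taken as the authors' FPKM values, deposited with 2 decimals, each pooled over the libraries of its group. The deposited fold change is a ratio of the WT to the mutant value, and differed from the ratio of the 2 columns by at most 0.00919 for genes at 5 FPKM or more in the mutant. The authors' q-value is deposited with 2 decimals, is at most 0.05 for the called genes, and is printed as 0 for 513 of the called Ascl1 genes and 197 of the called Ptf1a genes. How Cuffdiff estimated the spread of the single Ptf1a heterozygote library, and whether the Ascl1 and Ptf1a columns were normalised together, is not given in the sources used here. FPKM is relative to all mapped fragments, so a few abundant transcripts in 1 group lower the values of all other genes there. The median log2 change over 12535 genes was -0.00 in the Ascl1 comparison, -0.04 in the Ptf1a comparison and 0.00 between the heterozygotes, and no scaling tried moved a median by more than 0.1.

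The table held 23289 rows, of which 54 repeated another row exactly and were dropped, leaving 23235 genes. Locus starts were taken to count from 0, because the span of 2816 of 20809 genes with 1 GENCODE M21 entry of the same name equals the M21 span that way, against 459 genes with starts counted from 1. Positions are printed with starts raised by 1. A locus can be shared, with 4171 genes on a locus that another gene also has and up to 61 genes on 1 locus. No coordinate of another build was used.

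The plan, the gene lists, the rule for named genes and the alternatives not marked as added were fixed before the data were examined. The planned test was a moderated linear model of log2(FPKM + 1) per library. Since the table gives 1 value per group, no such model, no gene set test and no leave-one-out fit could be made, and the fallback written with the plan was used, namely the values and their ratio side by side. The authors' calls stand in for the test within each lineage. Changes are log2 ratios of (FPKM + 1), which understate the change of low genes, and folds in the text are ratios of the FPKM values themselves, given only where neither value is 0. A value of 0 is described as listed at 0, because it can be a failed estimate. Unadjusted p-values were not given, so that no call adjusted over the list alone could be made. Reads could not be recovered from the FPKM values. Low values of single-transcript genes, multiplied by transcript length, lay within 0.1 of a whole multiple of the best step for 27.5% to 36.7% of values, where 20% is due to chance, so depth stayed unknown.

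The 23 gene lists (inhibitory and excitatory neurons, dorsal progenitor factors, ventral neural tube, motor neurons, neural progenitors, Notch pathway, proneural targets, pan-neuronal genes, synapse and axon guidance, cell cycle, neural crest and sensory neurons, glial precursors, erythroid, endothelial, mesenchyme, macrophage and microglia, dissociation stress, p53 and apoptosis, ribosomal proteins, oxidative phosphorylation, Hox, and neuropeptides, receptors and channels) share some genes. Of their 509 entries, 1 was absent from the table and 1 was matched by an older symbol. Members called higher or lower by the authors were counted. The median change of members with a mean over the 4 columns of at least 1 FPKM was placed among 10000 random lists of the same size matched in 20 bins of mean level, for the 22 lists with at least 5 such genes, as a description of these group values. Overlaps of called genes were tested with Fisher's exact test, two-sided, over the 12535 genes with a mean of at least 1 FPKM. The 2 mutant comparisons share no library, and the comparison of the heterozygotes shares a column with each.

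Named genes followed the fixed rule: Ascl1 and Ptf1a, the 10 largest ratios of (FPKM + 1) in each direction among genes with at least 5 FPKM in either group (models left out), up to 4 called members of each list or otherwise up to 2, and 17 genes of dorsal neuron specification whatever their result. Because the second part chose small RNA genes, the 15 largest ratios per direction among called genes without small RNAs were added after the values were seen, and some called list members beyond 4 are also named for the same reason. The steps were tested on simulated data. With 20 genes of the Ascl1 comparison shifted by 0.5 on the log2 scale, 100% of 200 runs over 12535 genes placed the list outside the middle 95% of random lists, and 4.5% did so with no shift, with the same shares for the Ptf1a comparison. Changes were shuffled over genes in these runs, so the shares need not hold for lists of genes that vary together. Shifts smaller than 0.5 were not tried. The overlap test found 20 extra shared genes in 100% of runs and reported an overlap in 2% of runs of independent lists.

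Alternatives tried were a pseudocount of 0.1 or 0.5, no filter or a mean of at least 5 FPKM, median scaling and quantile normalisation. A q-value of at most 0.1 and a log2 change of at least 1 were tried too. Added after the data were seen were leaving out small RNA genes and a mean of at least 1 FPKM for the authors' calls. The overlap over every gene and median scaling for the lists were also added then. Intervals in the closing section are 95% bootstrap intervals from 10000 resamples of genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.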

Results

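The study measured mRNA levels in cells sorted from the neural tube of ICR mouse embryos at stage E11.5, when the dorsal spinal cord is making its inhibitory and excitatory neurons. Cells that had switched on the Ascl1 gene were sorted by green fluorescent protein (GFP) knocked into that gene, and cells of the Ptf1a lineage were sorted by an mCherry reporter driven by a Ptf1a enhancer region. Ascl1 and Ptf1a are basic helix-loop-helix transcription factors of dorsal neural progenitors. The 7 libraries fell into 4 groups. There were 2 libraries of Ascl1 heterozygotes, 2 of Ascl1 homozygous mutants, 1 of a Ptf1a heterozygote and 2 of Ptf1a homozygous mutants. The authors' deposited table held 1 FPKM value per group (a fragment count normalised to transcript length and to all mapped fragments) for 23235 genes, so that no spread between libraries could be computed, no value below has an SD, and the depth of each library is unknown. The values summed to 510957 in the Ascl1 heterozygote, 507984 in the Ascl1 mutant, 524671 in the Ptf1a heterozygote and 521789 in the Ptf1a mutant, where 5640, 5563, 4924 and 2561 genes were listed at 0. Its header calls the controls WT, whereas the sample labels describe heterozygotes only, and they are called heterozygotes here. The only test across replicates is the authors' own, with its q-values and its yes or no call per gene. "Rose" and "fell" are used below only of genes that the authors' deposited table calls changed, and all other differences are given as values. Gene positions are on the mm9 build.

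The labels were first set against the targeted genes. Ptf1a (chromosome 2, 19367290 to 19369128) stood at 20.5 FPKM in the Ptf1a heterozygote and 6.41 FPKM in the Ptf1a mutant, and it fell, with a q-value printed as 0 in the authors' deposited table. Ascl1 (chromosome 10, 86953786 to 86956405) rose in the column labelled Ascl1 mutant, from 105.8 to 179.2 FPKM. A knock-in can leave transcribed parts of the targeted gene in place, so a whole-gene FPKM checks neither genotype. Ptf1a also fell in the Ascl1 mutant, from 12.5 to 6.12 FPKM. Ascl1 stood at 117.9 FPKM in the Ptf1a heterozygote and 133.0 FPKM in the Ptf1a mutant and was not called.

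The first comparison asked what the loss of Ascl1 changes in cells that had switched on its locus. In the Ascl1 mutant, 16 of 28 genes of excitatory neurons and 16 of 28 genes that proneural factors are known to switch on fell, while 25 of 30 cell cycle genes rose, in the authors' deposited table. Lmx1b, a LIM-homeodomain factor of dorsal excitatory neurons (chromosome 2, 33420056 to 33496031), fell 9.74-fold, from 28.1 to 2.88 FPKM. Tlx3, a homeobox gene that selects the excitatory fate in the dorsal horn (chromosome 11, 33100752 to 33103588), fell 6.61-fold, from 42.0 to 6.35 FPKM. The Notch ligand gene Dll3 (chromosome 7, 29078574 to 29086804) fell 6.51-fold, from 97.2 to 14.9 FPKM. Pax2, a paired-box factor of inhibitory interneurons (chromosome 19, 44831884 to 44912359), fell from 120.4 to 69.7 FPKM. The authors' deposited table called 1196 genes in this comparison, of which 744 were higher and 452 lower in the mutant. The median size of the called changes was 0.69 on the log2(FPKM + 1) scale for the higher genes and 0.66 for the lower ones, and of the 22 lists with at least 5 genes above the level filter, 13 had a median outside the middle 95% of matched random lists.

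Of the 28 excitatory neuron genes listed, 16 fell and none rose in the authors' deposited table. Besides Lmx1b and Tlx3 they included Tlx1, from 4.88 to 1 FPKM, Phox2b, from 30.7 to 10.2 FPKM, and Otp, from 31.5 to 10.7 FPKM. Slc17a6, which encodes the vesicular glutamate transporter VGLUT2, fell 1.85-fold, from 25.7 to 13.9 FPKM, and Isl1 fell from 13.6 to 6.84 FPKM. The median change of the 23 members with a mean of at least 1 FPKM was -0.88 on the log2 scale, below all of 10000 random lists of the same size and mean level. Of the 25 inhibitory neuron genes, 12 fell and none rose, and the median change of 22 members was -0.53, again below all random lists. Lhx1 went from 124.2 to 83.7 FPKM, Lhx5 from 123.5 to 75.8 FPKM, and Slc32a1, the vesicular transporter of GABA and glycine, from 45.2 to 27.6 FPKM. The factor Tfap2b also fell, from 116.0 to 66.4 FPKM. So did 2 factors of ventral inhibitory neurons, Gata2, from 14.99 to 7.64 FPKM, and Gata3, from 15.75 to 9.94 FPKM. Gad1, which makes GABA, stood at 40.4 and 28.8 FPKM with a q-value of 0.06 in the authors' deposited table and was not called, and Prdm13 stood at 50.4 and 39.4 FPKM without a call.

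**Figure D1:**
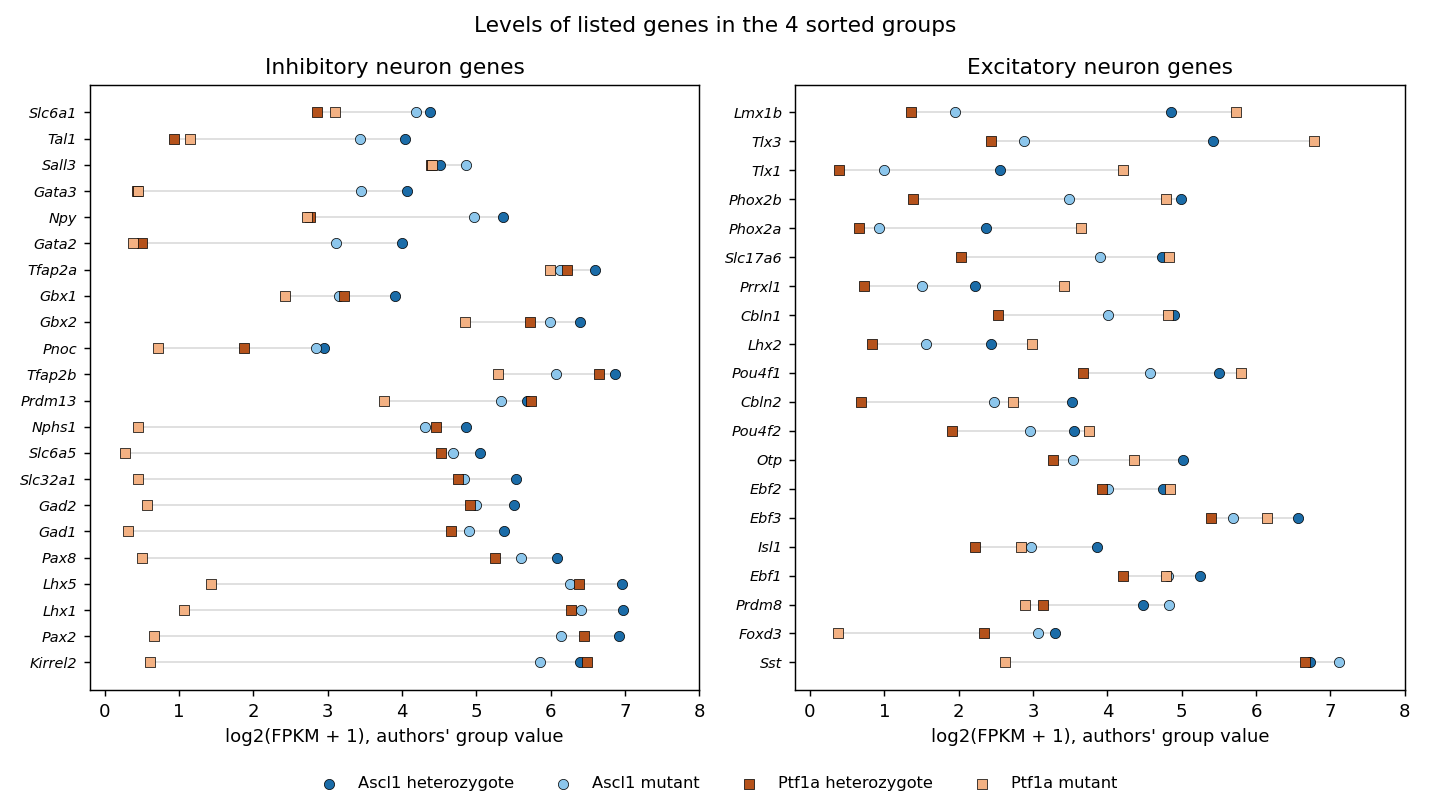
Authors' FPKM value of each listed inhibitory (left) and excitatory (right) neuron gene with at least 5 FPKM in any group, on a log2(FPKM + 1) axis, in the 4 sorted groups; each symbol is 1 group value with no error bar, since the table holds none. Most inhibitory genes have their lowest value in the Ptf1a mutant (Pax2 at 0.59 FPKM), and many excitatory genes have their highest value there (Tlx3 at 109.2 FPKM).

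Among 28 genes listed as targets of proneural factors, 16 fell and none rose in the authors' deposited table, with a median of -0.63 over all members, below all random lists. Cdc25b, a phosphatase that drives entry into mitosis, fell 5.91-fold, from 97.1 to 16.4 FPKM. Hes6 fell 2.68-fold, from 222.8 to 83.1 FPKM, Insm1 fell from 64.4 to 33.5 FPKM, and Dll1 fell from 102.3 to 54.8 FPKM. Members of the Notch pathway went both ways, with 6 of 28 lower and 4 higher in the authors' deposited table. The effector Hes5 fell 2.14-fold, from 66.4 to 31.0 FPKM, and Dll1, Dll3, Mfng, Numbl and Heyl fell with it, while Hes1 rose from 7.07 to 13.3 FPKM and Notch2, Notch3 and Jag1 rose. Pan-neuronal genes were lower in the mutant for all 25 members, 11 of them called, with a median of -0.55. Nefl, a neurofilament gene, fell from 126.9 to 69.9 FPKM, and Gap43, a growth cone gene, fell from 143.7 to 78.2 FPKM.

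The genes that rose included 25 of 30 cell cycle genes in the authors' deposited table, and none of that list fell. Their median was 0.67, above all random lists. Mcm6, a subunit of the replicative helicase, rose 2.52-fold, from 33.6 to 84.7 FPKM, Mcm3 rose from 27.6 to 64.0 FPKM, Mcm5 rose from 27.0 to 60.6 FPKM and the cyclin gene Ccnd2 rose from 28.2 to 61.3 FPKM. Of 24 neural progenitor genes, 11 rose and Hes5 alone fell in the authors' deposited table, with Slc1a3 going from 2.35 to 6.42 FPKM, Ednrb from 30.3 to 72.4 FPKM, Id2 from 46.1 to 85.4 FPKM and Sox2 from 72.5 to 127.6 FPKM. Of 25 transcription factors and signals of dorsal progenitors, 7 rose and 2 fell in the authors' deposited table. Msx2 rose 3.03-fold, from 3.78 to 11.45 FPKM, Gsx1 rose 2.51-fold, from 12.8 to 31.95 FPKM, and Pax3, Pax6, Msx3, Wnt1 and Wnt3 also rose, whereas Gsx2 fell from 15.95 to 10.04 FPKM and Neurog2 from 75.1 to 49.0 FPKM. Neurog1 stood at 9.77 and 12 FPKM without a call. Of 12 genes of oligodendrocyte and astrocyte precursors, Nfia, Nfib and Fgfr3 rose and Sox10 fell.

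The calls in the Hox list, which marks the level along the body axis, split by position in the cluster. Hoxc10 (chromosome 15, 102797227 to 102802328) rose 19.3-fold, from 0.56 to 10.8 FPKM, Hoxa10 rose from 1.75 to 7.36 FPKM and Hoxd9 rose from 0.69 to 3.88 FPKM, while Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxb8 and Hoxc4 fell, each by less than 2-fold. These 3 rises and 6 falls are the calls on 27 listed genes in the authors' deposited table. The list's median was -0.37, below all random lists, and its mean was -0.10.

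Medians of the dorsal progenitor, neural progenitor and glial precursor lists were 0.27, 0.32 and 0.73, outside the middle 95% of random lists. In the authors' deposited table Ntn1 and Efnb2 rose and Dcc, Plxna2 and Slit1 fell among 26 synapse and axon guidance genes. Ntrk2, Tfap2c and Ets1 rose and Sox10, Isl1 and Pou4f1 fell among 18 neural crest and sensory genes. Gabra2, Grik3 and Kcnq2 fell among 31 neuropeptide, receptor and channel genes, and 20 of the 22 members above the level filter had lower values, with a median of -0.27, outside the middle 95% of random lists. So were the medians of the synapse list, at -0.14, and the neural crest list, at -0.22, though both lay inside at a mean of at least 5 FPKM and the latter also with a pseudocount of 0.1. Of 17 ventral neural tube genes, Shh rose from 0.29 to 1.20 FPKM and Gli1 from 0.55 to 1.34 FPKM. Dcn rose from 1.01 to 3.79 FPKM among 18 mesenchyme genes. In the dissociation stress list Jun rose and Egr1 fell, and in the p53 and apoptosis list Casp8 rose and Cdkn1a and Pmaip1 fell. The lists of motor neuron, erythroid, endothelial and pericyte, macrophage and microglia, ribosomal protein and oxidative phosphorylation genes held 0 calls by the authors' Cuffdiff q-values, and unadjusted p-values were not given in the deposited table. The ribosomal list had a median of 0.18, above 99.6% of random lists, which quantile normalisation brought inside their middle 95%. For the ventral neural tube list the median and the mean differed in sign, at -0.13 and 0.04.

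By the rule fixed in advance for single values, the 10 largest ratios of (FPKM + 1) in each direction were to be named. They held 19 small RNA genes out of 20, and 18 of the 20 were listed at 0 in 1 of the 2 columns. Snord42a, for example, was listed at 2313 FPKM in the heterozygote and at 0 in the mutant. The other gene was Prkg1, at 400.2 and 0.79 FPKM without a call (0.68 and 0.75 FPKM in the Ptf1a heterozygote and mutant). The authors' deposited table called 2 of the 20. The called genes with the largest ratios outside this class are therefore given too, by a rule added after the values were seen. Beyond genes already named, those that fell included Nbl1, from 7.81 to 0.59 FPKM, Ppm1a, from 181.9 to 42.2 FPKM (41.8 and 37.3 FPKM in the Ptf1a heterozygote and mutant), Rassf4, from 28.3 to 8.13 FPKM, Plk3, from 53.7 to 18.9 FPKM, and Pcp4, from 24.8 to 8.45 FPKM. Capn10 fell from 47.3 to 15.6 FPKM (15.8 and 16.8 FPKM in the Ptf1a heterozygote and mutant). Trappc1 fell from 269.3 to 94.5 FPKM (87.2 and 90.25 FPKM there), and Fgf18 made up the rest. For Ppm1a, Capn10 and Trappc1 the Ascl1 heterozygote alone stood apart from the other groups, and the cause was not tested. Those that rose included Gpc3, 6.16-fold from 8.82 to 54.3 FPKM, Rnf144b, from 1 to 8.10 FPKM, Gdf10, 5.72-fold from 2.86 to 16.4 FPKM, Nppc, 5.02-fold from 4.84 to 24.3 FPKM, Sparcl1, 4.28-fold from 4.40 to 18.8 FPKM, and Eps8, from 1.55 to 8.50 FPKM, and the rest were Slc15a2, Pcsk6, Lamb1, H19, Gdpd2, Ifitm3 and Gja1. Requiring a log2 change of at least 1 in size as well left 169 of the 1196 genes in the authors' deposited table, 115 higher and 54 lower.

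The second comparison asked what the loss of Ptf1a changes in cells of its lineage. In the Ptf1a mutant 15 of 25 inhibitory neuron genes fell and 15 of 28 excitatory neuron genes rose in the authors' deposited table. Pax2 fell 146-fold, from 86.3 to 0.59 FPKM, Lhx1 fell 69.8-fold, from 76.0 to 1.09 FPKM, and Lhx5 fell 48.2-fold, from 81.9 to 1.70 FPKM. Tlx3 rose 24.7-fold, from 4.43 to 109.2 FPKM, Lmx1b rose 33.3-fold, from 1.57 to 52.2 FPKM, and Tlx1 rose from 0.31 to 17.5 FPKM. The authors' deposited table called 380 genes, 244 higher and 136 lower in the mutant, against a single heterozygote library. The median size of the called changes was 0.96 on the log2(FPKM + 1) scale for the higher genes and 0.95 for the lower ones. Of the 22 lists, 10 had a median outside the middle 95% of matched random lists.

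Of the 25 inhibitory neuron genes, 15 fell and none rose in the authors' deposited table, and the median of 22 members was -1.66, below all random lists. The genes for making and loading GABA and glycine were among them. Gad1 fell 101-fold, from 24.3 to 0.24 FPKM, Gad2 fell 60.6-fold, from 29.1 to 0.48 FPKM, Slc32a1 fell 70.1-fold, from 26.0 to 0.37 FPKM, and Slc6a5, the neuronal glycine transporter, fell from 21.9 to 0.21 FPKM. Kirrel2, a cell adhesion gene, fell 171-fold, from 88.7 to 0.52 FPKM, and its neighbour Nphs1 fell from 20.9 to 0.37 FPKM. Pax8 fell from 37.2 to 0.42 FPKM, and Prdm13, a zinc finger gene of the same lineage, fell from 52.1 to 12.5 FPKM. Gata2, Gata3 and Tal1, factors of ventral inhibitory neurons, stood between 0.30 and 1.21 FPKM in both Ptf1a groups without a call. Tfap2a, at 73.8 and 62.8 FPKM, and Npy, at 5.79 and 5.61 FPKM, were not called either. Strand was not stated for these libraries, and the predicted gene Gm14204, which ends just before Slc32a1 starts, fell from 23.6 to 3.51 FPKM.

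Of the 28 excitatory neuron genes, 15 rose and 2 fell in the authors' deposited table, and the median of 23 members was 1.84, above all random lists. Slc17a6 rose 8.94-fold, from 3.08 to 27.6 FPKM, Phox2b rose from 1.61 to 26.6 FPKM, Prrxl1 from 0.65 to 9.71 FPKM, Pou4f1 from 11.8 to 54.5 FPKM and Cbln1 from 4.77 to 27.3 FPKM. Tac1 was listed at 0 in the heterozygote and rose to 1.88 FPKM. The 2 members that fell were the peptide gene Sst, from 99.6 to 5.17 FPKM, and Foxd3, from 4.05 to 0.30 FPKM. Isl1 stood at 3.68 and 6.16 FPKM with a q-value of 0.11 in the authors' deposited table, without a call. The model C130021I20Rik, whose locus lies next to Lmx1b, rose from 1.88 to 68.6 FPKM.

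Progenitor and cell cycle genes had few calls in this comparison. None of 25 dorsal progenitor genes was called by the authors' Cuffdiff q-values in the deposited table, Id1 and Id4 alone fell among 24 neural progenitor genes, and Ccnd2 alone fell among 30 cell cycle genes, from 56.6 to 24.3 FPKM. The cell cycle list as a whole had a median of -0.13, with 24 of 30 members lower, above 0.32% of random lists. Gsx1 stood at 16.5 and 20.5 FPKM, Neurog2 at 54.8 and 38.0 FPKM, Neurog1 at 1.24 and 1.15 FPKM, Dll1 at 76.6 and 75.8 FPKM and Hes5 at 127.9 and 149.8 FPKM. Dll3 rose from 69.8 to 113.8 FPKM, and with it Mfng, Gadd45g and Neurod4 were the 4 of 28 proneural target genes called higher in the authors' deposited table. Dll3 and Mfng were also the 2 calls among 28 Notch pathway genes. Of 25 pan-neuronal genes, Nefl, Nefm, Gap43 and L1cam rose in the authors' deposited table, Nefl from 21.7 to 98.0 FPKM, while the median of the list was 0.04 and lay inside the middle 95% of random lists under quantile normalisation or at a mean of at least 5 FPKM.

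Among the other lists, Ephb1, Nrp2 and Chl1 rose of the synapse and axon guidance genes. Of the neuropeptide, receptor and channel genes Tac1 and Gabra2 rose and Sst, Pnoc and Gria1 fell. Ntrk3 and Pou4f1 rose and Foxd3 fell in the neural crest and sensory list. Pdgfra, a member of both the glial precursor and the mesenchyme list, rose from 1.05 to 2.08 FPKM, and Ret, from the motor neuron list, fell from 0.96 to 0.34 FPKM. The ventral neural tube, endothelial and pericyte, dissociation stress, p53 and apoptosis, ribosomal protein, oxidative phosphorylation and Hox lists held 0 calls by the authors' Cuffdiff q-values in the deposited table. Outside the middle 95% of random lists lay the medians of the synapse list (0.12), the neuropeptide, receptor and channel list (-0.24, inside at a mean of at least 5 FPKM), the glial precursor list (-0.24, inside with a pseudocount of 0.1 or quantile normalisation) and the proneural target list (0.07, inside under quantile normalisation and at a mean of at least 5 FPKM, where it was -0.02). Median and mean differed in sign for the Notch list (-0.06 and 0.06), the stress list (-0.04 and 0.02) and the Hox list (0.03 and -0.02).

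Of the 7 erythroid genes above the level filter, 6 had higher values in the Ptf1a mutant in the same comparison, and the adult globin gene Hbb-b1 had a lower one (14.55 and 9.99 FPKM). Hbb-b2, given the same locus as Hbb-b1, stood at 5.87 and 8.99 FPKM in the Ptf1a heterozygote and mutant. The globin entry Beta-s stood at 12.06 and 23.74 FPKM there, and none of these entries was called. The embryonic globin gene Hbb-bh1 rose from 268.6 to 488.1 FPKM, and Slc4a1, which encodes the anion exchanger of the red cell membrane, rose from 5.70 to 9.78 FPKM, the 2 calls among 13 erythroid genes in the authors' deposited table. The globin genes Hba-x stood at 723.8 and 1290 FPKM and Hbb-y at 1307 and 2037 FPKM without a call. The list had a median of 0.68, above all random lists, and made up 0.445% of all FPKM in the Ptf1a heterozygote and 0.740% in the Ptf1a mutant, against 0.00764% and 0.00838% in the Ascl1 heterozygote and mutant. Macrophage and microglia genes had a median of 0.52, above 99.9% of random lists, with 0 calls by the authors' Cuffdiff q-values in the deposited table, and Cx3cr1 stood at 1.38 and 2.41 FPKM.

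The rule for the largest ratios of (FPKM + 1) named 20 small RNA genes here, 19 of them listed at 0 in 1 column and none called in the authors' deposited table. Scarna9, for example, was listed at 0 in the heterozygote and at 876.6 FPKM in the mutant. By the added rule, the called genes with the largest falls beyond those named above were Slc30a3, a vesicular zinc transporter gene, from 15.7 to 0.21 FPKM, Cacna2d3, a calcium channel subunit gene, from 11.8 to 0.84 FPKM, Cartpt, from 18.8 to 1.98 FPKM, and Nrxn3, from 7.78 to 0.75 FPKM. The largest rises beyond those named were Tmem163, from 3.72 to 30.2 FPKM, Calb2, a calcium-binding protein gene, 11.8-fold from 1.07 to 12.6 FPKM, Nrn1, from 3.24 to 26.7 FPKM, Adcyap1, a neuropeptide gene, 9.02-fold from 1.69 to 15.2 FPKM, and Crabp1, a retinoic acid binding protein gene, 4.54-fold from 285.9 to 1298 FPKM. Cacna2d1, from 2.72 to 16.8 FPKM, and Lhx2, from 0.79 to 6.95 FPKM, were also in this set. So was Lars2, from 22.9 to 112.0 FPKM, which stood at 328.4 and 502.1 FPKM in the Ascl1 heterozygote and mutant. Of the 380 genes called in the authors' deposited table, 210 had a mean of at least 5 FPKM and 177 a log2 change of at least 1 in size.

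**Figure D2:**
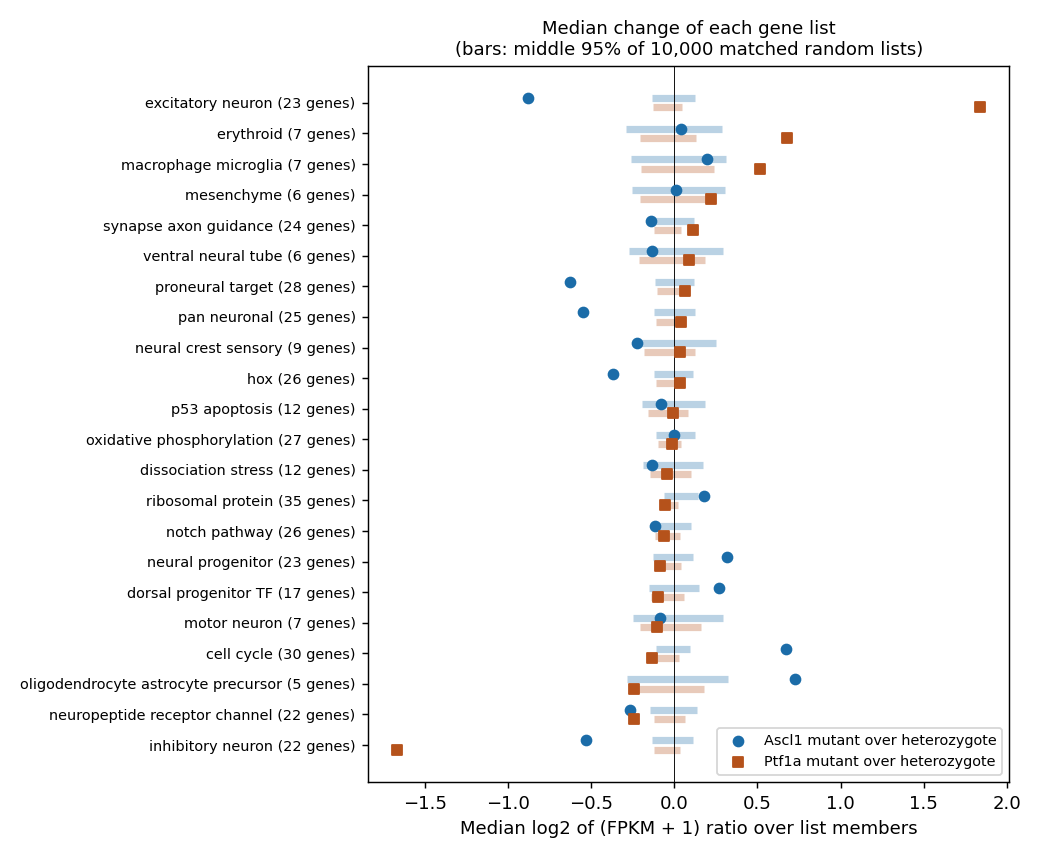
Median log2 ratio of (FPKM + 1), mutant over heterozygote, of each gene list fixed in advance (members with a mean of at least 1 FPKM), in the Ascl1 mutant (circles) and the Ptf1a mutant (squares); the bars span the middle 95% of 10000 random lists of the same size and mean level, and the symbols carry no replicate error. The excitatory list lies at -0.88 in the Ascl1 mutant and 1.84 in the Ptf1a mutant, and the inhibitory list at -0.53 and -1.66.

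The third comparison set the changes in the 2 mutants against each other, to ask which genes depend on both factors. The calls overlapped mostly among genes that fell in the Ascl1 mutant, and those genes went in both directions in the Ptf1a mutant. Of 12535 genes with a mean of at least 1 FPKM, 63 fell in the Ascl1 mutant and rose in the Ptf1a mutant in the authors' deposited table, where 7.29 would be shared by independent lists. They included Lmx1b, Tlx1, Tlx3, Phox2b, Slc17a6, Pou4f1, Calb2, Adcyap1, Nefl, Dll3 and Mfng. A further 32 genes fell in both mutants, against 4.65 for independent lists, among them Ptf1a itself, Pax2, Lhx1, Lhx5, Slc32a1, Kirrel2, Skor1 and Skor2. Fisher's exact test, two-sided, gave an odds ratio of 13.8 and p = 4.34e-42 for the first overlap and 9.34 and p = 1.94e-18 for the second, or 1.74e-41 and 3.88e-18 after Benjamini-Hochberg adjustment over the 4 pairs of directions. Only 1 gene, Rmrp, which encodes the RNA part of an RNase, was called higher in both, against 11.8 for independent lists (odds ratio 0.0789, adjusted p = 0.000152 by Fisher's exact test). The 8 genes that rose in the Ascl1 mutant and fell in the Ptf1a mutant, such as Gpc3, Gpc4, Ccnd2, Dhrs3 and Cdh11, numbered about as many as the 7.55 of independent lists (odds ratio 1.06, adjusted p = 0.849 by Fisher's exact test). These tests treat genes as independent, which genes of 1 cell type are not. Across the 12535 genes the log2 changes in the 2 mutants had a Pearson correlation of -0.063 (-0.19 without small RNA genes) and a Spearman correlation of -0.30, as a description of genes within 4 group values.

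**Figure D3:**
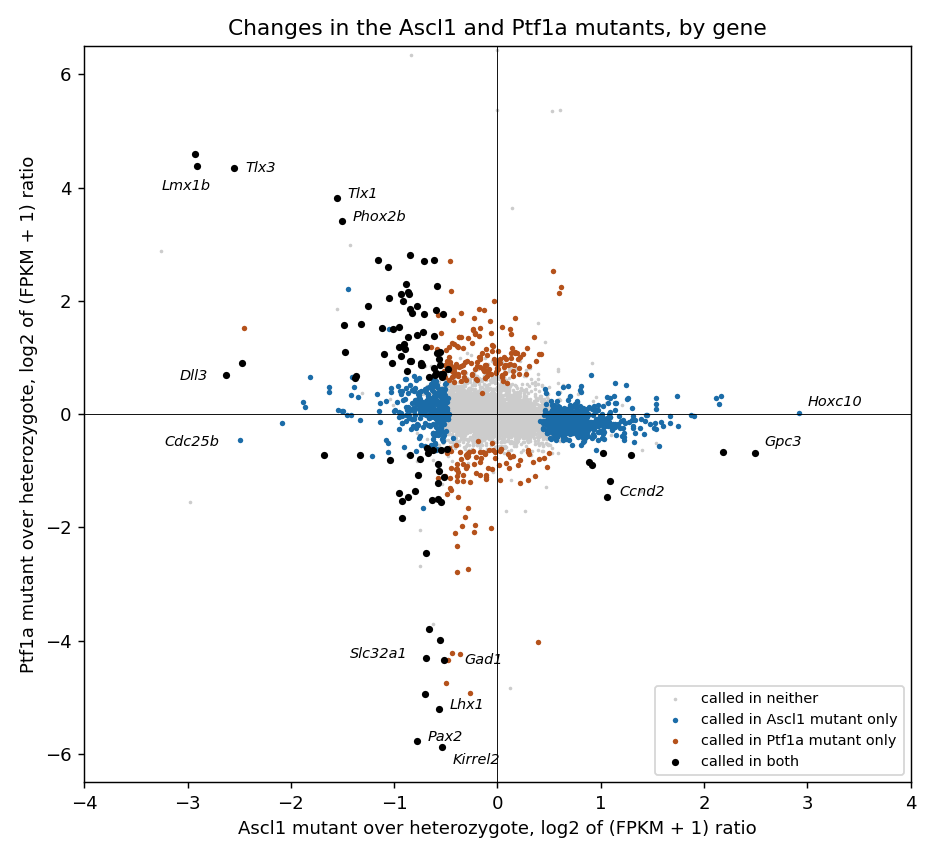
Log2 ratio of (FPKM + 1), mutant over heterozygote, in the Ascl1 mutant (horizontal) and the Ptf1a mutant (vertical) for each gene with a mean of at least 1 FPKM, small RNA genes left out; each point is 1 gene, coloured by the authors' calls, with no error bar, and 2 genes lie outside the axes. The genes called in both lie almost all left of 0, with Lmx1b and Tlx3 at the top and Pax2, Kirrel2 and Lhx1 at the bottom.

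The difference between the 2 changes (Ptf1a mutant minus Ascl1 mutant) was at least 1 on the log2(FPKM + 1) scale in size for 801 genes, 434 above and 367 below 0, and no test of this difference was possible with 1 value per group. Which side held more genes turned with the setting, at 273 above and 292 below without small RNA genes and 596 and 602 with a pseudocount of 0.1. It was 7.28 for Lmx1b, 6.89 for Tlx3, 5.37 for Tlx1 and 3.65 for Slc17a6, and -5.00 for Pax2, -4.64 for Lhx1, -3.88 for Gad1 and -4.42 for Sst. The median difference of the excitatory list was 3.02 and that of the inhibitory list was -1.34, above and below all random lists. Cell cycle genes had a median difference of -0.79, below all random lists, and proneural target genes one of 0.78, above all of them.

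The last comparison set the Ptf1a heterozygote against the Ascl1 heterozygote. The lineage, the reporter and the sort differ together here, and the single Ptf1a library has no replicate, so that the values are given without a test. Pan-neuronal genes had lower values and cell cycle genes higher values in the Ptf1a heterozygote. All 25 pan-neuronal genes were lower, with a median of -1.10 on the log2 scale, and all 30 cell cycle genes were higher, with a median of 1.28. Of neural progenitor genes 21 of 23 were higher, with a median of 0.77, while dorsal progenitor genes had a median of 0.03, inside the random lists, with 10 higher and 7 lower. Ednrb, for example, stood at 30.3 FPKM in the Ascl1 and 139.1 FPKM in the Ptf1a heterozygote. All 23 excitatory neuron genes above the level filter were lower in the Ptf1a heterozygote, with a median of -1.65, and inhibitory neuron genes were lower by a median of -0.67. Lmx1b was 17.9-fold lower, Tlx1 15.7-fold lower, Tlx3 9.47-fold lower and Slc17a6 8.35-fold lower, whereas Pax2 was 1.40-fold lower, Lhx1 1.63-fold lower, Lhx5 1.51-fold lower and Gad1 1.66-fold lower. Ventral neural tube genes had a median of -2.06 over 6 members, with 4 lower and 2 higher. Of that list, Vsx2 stood at 16.1 and 0.19 FPKM. Lhx3, a factor of motor neurons and V2 interneurons from the motor neuron list, stood at 20.1 and 0.17 FPKM. Gata3, from the inhibitory list, stood at 15.8 and 0.35 FPKM, and Sox14 at 9.77 and 0.11 FPKM. Erythroid genes went the other way, with Hbb-y at 22.1 FPKM in the Ascl1 and 1307 FPKM in the Ptf1a heterozygote, and all 7 macrophage and microglia genes above the filter were higher, with a median of 1.31. Ptf1a stood at 12.5 and 20.5 FPKM, Prdm13 at 50.4 and 52.1 FPKM, Isl1 at 13.6 and 3.68 FPKM, Neurog1 at 9.77 and 1.24 FPKM, Neurog2 at 75.1 and 54.8 FPKM, Gsx1 at 12.8 and 16.5 FPKM, Dll1 at 102.3 and 76.6 FPKM, Dll3 at 97.2 and 69.8 FPKM and Hes5 at 66.4 and 127.9 FPKM. In all, 1409 genes differed by at least 1 on the log2(FPKM + 1) scale, 673 higher and 736 lower in the Ptf1a heterozygote. The larger side turned under quantile normalisation (706 higher, 680 lower) and at a mean of at least 5 FPKM (537 and 519), and the counts were 698 and 699 under median scaling.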

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

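No test in this part was chosen after its result was seen. Genes called in opposite directions in the mutants of Ascl1 and Ptf1a stood out. Of the genes with a mean of at least 1 FPKM, 63, among them Lmx1b, Tlx3, Phox2b and Slc17a6, were called lower in the Ascl1 mutant and higher in the Ptf1a mutant in the authors' deposited table. The reverse, higher in the Ascl1 mutant and lower in the Ptf1a mutant, was called there for 8 of these genes, Gpc3, Gpc4, Ccnd2, Dhrs3, Cdh11, Ildr2, Rnf144b and A930038C07Rik. Independent lists would share 7.29 genes of the first kind and 7.55 of the second. The set of 63 was far larger than that, while the set of 8 was about as large. For both sets the difference was not tested gene by gene, since each group has 1 value, and the effects are in cells sorted with different reporters.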

How the results depend on the processing

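The settings that left out small RNA genes, the mean of at least 1 FPKM for the authors' calls, the overlap over every gene and median scaling for the lists were tests chosen after the data were seen. Requiring a log2 change of at least 1 left 169 of 1196 calls in the Ascl1 mutant and 177 of 380 in the Ptf1a mutant in the authors' deposited table, and a mean of at least 5 FPKM left 210 of the 380; fewer genes are counted by construction. At that mean, 6 lists instead of 10 lay outside the random lists in the Ptf1a mutant, where fewer members are left. Fewer lists kept at least 5 members, and the erythroid, macrophage and glial precursor lists, outside before, were not placed at all. The neural crest list (median 0.61) and the Hox list (0.06) newly lay outside. The other alternatives kept the counts within 1.5 times, namely 6 of 7 for the Ascl1 calls, 5 of 7 for the Ptf1a calls, all 7 for the heterozygotes (1056 to 1981 genes), all 7 for the difference of the changes (565 to 1198 genes), both for the overlap (84 and 105 genes), all 4 for the Ascl1 lists and 3 of 4 for the Ptf1a lists. Median scaling, 1 of the 4 for the lists, shifts a list and its random lists alike and could not change those counts. All 1196 and 380 calls kept their direction under median scaling and quantile normalisation. These scalings moved the median changes little, while the sizes of the called changes had lower quartiles of 0.57 to 0.76. A turn in direction was thus unlikely from the start. Across genes, the Pearson correlation of the 2 changes moved from -0.063 to -0.19 without small RNA genes. The Spearman correlation, which uses ranks, went only from -0.30 to -0.32, so the move lay mainly in the sizes of the changes. The cause was not tested further. No paired analysis was possible because the table gives 1 value per group and its columns carry no replicate number. For the same reason leaving out a library, the other linear models, the set tests and an unadjusted p under 0.01 were not run, and pseudocounts do not enter the authors' calls. Depth is unknown, so no limit for genes listed at 0 can be given.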

Other observations

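The glial, laminin, glypican, channel, receptor subunit and imprinted gene groups, the sex-linked genes, the tests on the share of neurons, the Hox test with a pseudocount of 1 and the test without the highest receptor gene were chosen only after the results were seen. In the Ascl1 mutant 8 of 12 radial glia and astrocyte genes rose in the authors' deposited table, and none was called in the Ptf1a mutant by Cuffdiff q-values. Gja1, a gap junction gene, rose from 14.4 to 43.8 FPKM, Sparc, a matrix protein gene, from 19.1 to 57.2 FPKM, and Hopx from 9.55 to 25.03 FPKM. Of 4 laminin genes 3 rose (Lamb1 from 1.35 to 6.49 FPKM), and of 6 glypican genes Gpc3, Gpc4 and Gpc6 rose in the authors' deposited table, where Gpc1 (45.3 and 37.5 FPKM) and Gpc2 (307.5 and 210.9 FPKM) were not called, while Gpc3 and Gpc4 fell in the Ptf1a mutant, Gpc4 from 8.26 to 2.34 FPKM.

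In the Ptf1a mutant the auxiliary subunits of calcium channels went in opposite directions, with Cacna2d1 rising from 2.72 to 16.8 FPKM and Cacna2d2 and Cacna2d3 falling from 16.2 to 5.21 FPKM and from 11.8 to 0.84 FPKM. Of 6 nicotinic receptor subunits, Chrna3 (8.95 to 25.01 FPKM), Chrna4 (27.2 to 52.95 FPKM) and Chrnb4 (2.48 to 5.34 FPKM) rose there, and Chrna3 and Chrna4 fell in the Ascl1 mutant, by the calls in the authors' deposited table. Of 14 imprinted genes, H19, Igf2, Grb10 and Mest rose and Cdkn1c and Dlk1 fell in the Ascl1 mutant, H19 from 22.7 to 74.4 FPKM, while Dlk1 (8.31 to 30.7 FPKM) and Peg10 (25.1 to 83.2 FPKM) rose in the Ptf1a mutant. The Y-linked genes Ddx3y, from 13.01 to 7.2 FPKM, and Uty, from 7.82 to 4.05 FPKM, fell in the Ptf1a mutant in the authors' deposited table. Embryo sex was not taken into account, and the Ptf1a heterozygote is a single library. A different share of male embryos cannot be told apart from an effect of the genotype here.

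Several posterior Hox genes were higher in the column labelled Ascl1 mutant, with 6 of 8 measured genes of groups 9 to 13 above the heterozygote and 3 called, while 21 of 23 genes of groups 1 to 8 were lower, 7 of them called in the authors' deposited table (Hoxb1, outside the fixed list, among them). Hoxb9 stood at 256.05 and 185.83 FPKM, Hoxc9 at 19.96 and 19.58 FPKM, and Hoxa9, counted as higher, at 17.01 and 17.85 FPKM. The other higher genes stood at 1.75 FPKM or less in the heterozygote. A larger share of dividing progenitors was weighed with the Ptf1a heterozygote, which had higher cell cycle values. Its posterior Hox values lay below those of the Ascl1 mutant by a median log2 ratio of -0.65 (interval -2.58 to -0.14) with a pseudocount of 0.1. With the pseudocount of 1 used elsewhere the median was -0.47. The bound of -0.5 set beforehand named no pseudocount, and only the median of -0.65 met it. That bound was wrongly chosen, since it sets another lineage, reporter and sort against a change within the Ascl1 groups, so this explanation stays open: Hoxc10, Hoxd9 and Hoxa10 were higher in the Ptf1a than in the Ascl1 heterozygote, Hoxa9, Hoxb9 and Hoxc9 were lower, Hoxd10 stood at 0.06 and 0.02 FPKM and Hoxd11 was listed at 0 in both. Tissue from a more caudal level may be the source and cannot be told apart from an effect of the genotype, because 100% of the genes of groups 11 to 13 that could be used were higher in the mutant but only 1, Hoxd11 (listed at 0 and at 0.50 FPKM), reached the level needed. An effect of Ascl1 on Hox genes stays open and was not tested.

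Neuronal genes as a class were lower in the Ascl1 mutant, so a smaller share of neurons among the sorted cells may lower fate genes without any change per neuron. For the inhibitory list the median change differed from that of the pan-neuronal list by 0.019 on the log2 scale (interval -0.10 to 0.15), which such a share would give. For the excitatory list the difference was -0.33 (interval -0.92 to -0.16), so its values were lowered further than those of the pan-neuronal list. A smaller share of neurons would lower both lists alike only if the other sorted cells expressed neither, which was not tested. That share therefore stays open as the whole cause there. A specific need of excitatory neurons for Ascl1 stays open as a biological explanation. The intervals cover the choice of genes and not the spread between libraries.

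Fewer genes were listed at 0 in the Ptf1a mutant, whose value pools 2 libraries, while the Ptf1a heterozygote value comes from 1. A gene could thus escape 0 more easily in the mutant by design, though both Ascl1 values also pool 2 libraries. Of 1437 olfactory and vomeronasal receptor genes 861 were above 0 in the Ptf1a mutant, against 321 in the Ptf1a heterozygote, 63 in the Ascl1 mutant and 53 in the Ascl1 heterozygote. Deeper sequencing alone would leave their summed FPKM level, and the sum was 1.70 times higher (interval 1.52 to 2.76), which lies between the bounds set beforehand. Of the sum in the mutant 56.7% came from Olfr856-ps1, and without it the ratio was 2.30 (interval 2.1 to 2.91), which argues against depth alone for the other receptor genes. A higher background of reads from outside mature transcripts is consistent with the lower bound of 1.52. The authors' deposited table called 5 of these receptor genes higher in the Ptf1a mutant, and whether other calls there carry such a background was not tested. Reads shared between near-identical copies were not tested, and no biological explanation was tested.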
